A study of Xenopus laevis with 6 samples.

How the data were processed

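RNA was measured in 6 libraries from the optic tectum of Xenopus laevis tadpoles at stage 46. Per the labels, 3 libraries came from neural progenitor-enriched material of animals kept in the dark (NPC) and 3 from immature neuron-enriched material of animals given visual stimulation (IN), each numbered 1 to 3. Per the labels' protocols, total RNA was extracted and treated with DNase, cDNA was sheared, and libraries were sequenced as single-end reads of 100 bases on a HiSeq instrument. Population and visual condition coincided in all 6 libraries, so their contributions could not be separated. How the populations were enriched is not given in the sources used here.

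The authors deposited 3 tables of whole-number read counts per gene or transcript, not normalized. Per the sheet names of the deposited tables, they hold STAR alignments counted over mRNA, STAR alignments counted over coding sequence, and TopHat2 alignments counted over coding sequence. FastQC, Trimmomatic, HTSeq and DESeq2 are also listed, per the submitters' processing notes, with no role, order or version. Aligner versions, the strand setting, the counting mode and the treatment of reads that match several places are not given in the sources used here. Without them, reads of near-identical L and S gene copies and of overlapping or antisense genes may have been dropped or assigned to either gene, so values of single copies are uncertain to that extent. Count columns were named by a letter and a number; D was read as dark (NPC), L as light (IN), and the numbers as those of the sample titles. Coordinates and gene symbols came from the annotation the authors deposited, which per the file headers is for genome build 9.1 with annotation version 1.8.3.1, although the name of the deposited annotation gives version 1.8.3.2; positions are 1-based. Of 45099 genes, 23600 carried a symbol. X. laevis is allotetraploid, and the suffixes .L and .S mark the copies on its long and short subgenomes.

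The STAR mRNA counts were the main table. Library totals ran from 8422751 to 9914191 counted reads. Genes with enough reads (filterByExpr, 19158 genes, 15868 of them with a symbol) were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood test, robust, 2-sided, R 4.3.3), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Log2 fold changes are IN minus NPC, and levels are CPM, read counts scaled to a common library size, after TMM scaling, given as mean ± SD. At the median gene the standard error was 1.41 on the log2 scale and the 95% interval reached 2.94 to each side. Reads without molecular identifiers are not independent molecules, so counting error alone understates the uncertainty of a count, also of a count of 0. The labels do not say that libraries came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical.

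Fixed gene lists, 35 in all, were tested with limma 3.58.1 (camera on log2 CPM with prior count 2 and a preset inter-gene correlation of 0.01), with Benjamini-Hochberg adjustment over the 33 lists with at least 5 tested genes. Camera with an estimated correlation and fry were run as alternatives. The summed CPM of a list per library was compared by an exact permutation test, 2-sided, whose smallest possible p for 3 against 3 is 0.1. Both L and S copies counted as members. The named genes were all copies of brca1 and elk1, up to 10 genes per direction past the threshold with a mean of at least 5 CPM, no overlap between groups and a gene symbol, and from each list up to 4 members past the threshold or, where none passed, up to 2 of lowest p. The grouping, tests, lists, naming rule and first alternatives were fixed before the data were examined. A filter at a mean of 50 CPM, the summed-CPM test, the comparisons between replicate numbers, the 10 genes per direction of lowest p and the levels of the most abundant list members were added after the data were seen.

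Alternatives were median-of-ratios and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, each coding-sequence table, the replicate number as a block, each library left out, L and S copies summed, and thresholds of 0.01 and 0.1. The code was tested on simulated counts with 200 changed genes. With the dispersion estimated from these libraries (18002 genes passing the filter), edgeR recovered 5% of genes changed 4-fold and 64% of genes changed 16-fold with 5 false calls, DESeq2 recovered 10% and 65% with 127 false calls, and limma-voom 1% and 44% with 3 false calls. With a dispersion of 0.05 (19102 genes), edgeR recovered 100% of both sizes with 10 false calls. A shift of 1 log2 unit in all members of the mitosis or synapse list was recovered by camera (adjusted p 2.38e-05 and 1.22e-06), and a shift of 0.5 was not (0.855 and 0.411). Simulated genes were drawn independently, in 1 run per setting. In the real libraries the estimated inter-gene correlation was 0.159 for mitosis and 0.011 for synapse genes. The simulation therefore overstates what camera can recover in correlated lists such as mitosis. Figures were drawn with matplotlib 3.10.9.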

Results

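Transcript levels were compared between neural progenitor-enriched, dark-exposed (NPC) and immature neuron-enriched, visually stimulated (IN) optic tectum, the main visual centre of the tadpole midbrain, with 3 libraries in each group. The mRNA table held 8422751, 9655246 and 8480161 counted reads in the NPC libraries and 9388103, 9747548 and 9914191 in the IN libraries. Reads were counted for 21182 to 24752 genes per library. A gene with no symbol, Xelaev18000045m.g (build 9.1, Scaffold1045, 1830 to 2841, plus strand), took 10.7% to 15.2% of reads, and ltk.S (8S, 5418366 to 5522166, minus strand), a receptor tyrosine kinase, took 1.27% to 3.72%. Population and visual condition coincided in every library.

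The series names BRCA1, a DNA repair protein, and ELK-1, a transcription factor phosphorylated by ERK, so their transcripts were examined first. The only annotated copy of brca1, brca1.L (9_10L, 29343116 to 29399294, minus strand), was at 22.5 ± 8.04 CPM in NPC and 4.25 ± 1.33 CPM in IN (SD, n = 3 each). Its reads were 125, 223 and 208 in NPC and 36, 57 and 33 in IN, without overlap between groups. elk1.S (8S, 26221773 to 26230798, plus strand) was at 54.3 ± 34.3 CPM in NPC and 13.8 ± 3.07 CPM in IN, also without overlap. Its other copy, elk1.L (8L, 1039937 to 1049684, minus strand), overlapped, at 36.0 ± 21.9 and 18.2 ± 15.4 CPM. The log2 fold change (IN minus NPC) was -2.40 (SE 1.53) for brca1.L, -1.98 (SE 1.04) for elk1.S and -0.98 (SE 1.19) for elk1.L. None passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (unadjusted p 0.133, 0.0712 and 0.417, adjusted p 1 for each), and the exact permutation p was 0.1 for brca1.L and elk1.S, the smallest that 3 against 3 can give, and 0.4 for elk1.L. Across alternatives the adjusted p ran from 0.557 to 1 for brca1.L and from 0.487 to 1 for elk1.S.

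**Figure D1:**
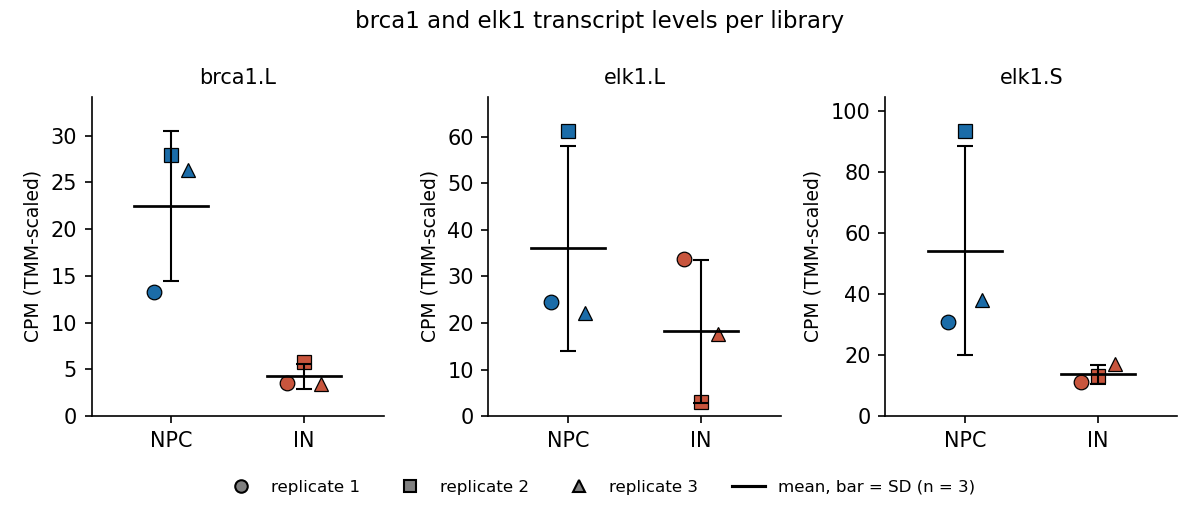
TMM-scaled CPM (vertical axis) of brca1.L, elk1.L and elk1.S in each NPC and IN library (points, shaped by replicate number), with the mean (line) and SD (bar, n = 3). The IN points of brca1.L and elk1.S lie below all NPC points, while those of elk1.L overlap; none of the 3 differences passed the test.

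The counted part of the transcript mattered for elk1. Over coding sequence with STAR, elk1.S had 174, 437 and 57 reads in NPC and 0, 0 and 1 in IN, while over the whole mRNA the IN libraries held 112, 129 and 166 reads. The coding reads summed over libraries, 668 against 1, gave an NPC to IN ratio of 777 (95% exact interval 139 to 30740). That interval holds counting error only and leaves out the spread between libraries. edgeR's log2 fold change was -9.23 (SE 2.35, unadjusted p 0.00072, adjusted p 0.989). With TopHat2, elk1.S had 167, 394 and 49 coding reads in NPC and 0, 0 and 6 in IN. Its log2 fold change was then -7.00 (SE 2.19, unadjusted p 0.00432, adjusted p 0.999, edgeR). elk1.L had 31, 150 and 6 coding reads in NPC and 190, 0 and 172 in IN, so its fold change turned to 0.74 with STAR and 0.96 with TopHat2 coding counts. brca1.L had 96, 187 and 203 coding reads in NPC and 3, 50 and 30 in IN. None of these passed after adjustment.

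Over all genes, 0 of 19158 passed edgeR's quasi-likelihood test (smallest adjusted p 0.638, for snx16.S), and 658 (3.43%, 369 higher in NPC and 289 higher in IN) had an unadjusted p under 0.05, where 958 would be expected by chance. DESeq2 called 88 genes, 44 in each direction, and limma-voom 0. DESeq2 made 127 false calls in counts simulated with the dispersion of these libraries, so its 88 calls are not set apart from false ones. Among genes named from the lists, DESeq2 called chrnb2.S, ube2c.L, wnt1.L, fancd2.L, mcl1.L, rxrb.S and ndufc1.L, and edgeR without a filter on reads called nefl.L. In 22 of the 88, 1 group held at most 3 reads in total. In 1678 genes (8.76%) the groups did not overlap, against 10% by chance. The biological coefficient of variation was 111%, so most single-gene differences were within the spread between replicates.

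Among the 10 genes of lowest p in each direction, chosen after their values were seen, chrnb2.S, a nicotinic acetylcholine receptor subunit, had 2167, 2595 and 758 reads in NPC and 377, 327 and 206 in IN (log2 fold change -2.83, SE 0.68). lrp8.S, a reelin receptor, was at 133 ± 55.6 and 17.3 ± 8.66 CPM, jak2.L, a cytokine receptor kinase, at 77.8 ± 52.1 and 4.90 ± 1.36, and ift172.L, an intraflagellar transport protein, at 102 ± 39.9 and 6.35 ± 7.42. In the other direction, rap2b.L, a small GTPase, had 1, 1 and 1 reads in NPC and 178, 259 and 286 in IN, and dcakd.L had 0, 1 and 0 against 233, 159 and 503. snx16.S, a sorting nexin, had 33, 3268 and 44 reads in NPC and 2, 1 and 5 in IN, so a single library held most of them. None passed edgeR's test.

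Of 33 lists tested with camera, 0 passed (2 at an unadjusted p under 0.05), 0 passed with an estimated correlation, and fry called 0 lists in 1 direction. Fry in either direction called 1 list, cholesterol and sterol synthesis (adjusted p 0.0119). Its members went both ways, with fold changes of 19 above 0 and 22 below (adjusted p in 1 direction 0.944 by camera and 0.998 by fry). Its sum was 1438 ± 258 CPM in NPC and 1164 ± 113 in IN. By lowest p, ebp.L, a sterol isomerase, had 70, 31 and 22 reads in NPC and 0, 0 and 0 in IN, and nsdhl.L 226, 1163 and 687 against 98, 267 and 168. DESeq2 statistics and limma-voom each gave 0 lists. The 2 lists at an unadjusted p under 0.05 were mitosis, higher in IN (p 0.0324, adjusted p 0.579, p 0.447 with an estimated correlation), and choroid plexus, lower in IN (p 0.0351, adjusted p 0.579, p 0.172 with an estimated correlation). No list member passed over all genes; adjusted over the list alone, 2 did, chrnb2.S among neurotransmitter receptors (adjusted p 0.022, edgeR) and pde6h.L, a cone phosphodiesterase subunit, among retina and lens genes (adjusted p 0.0293, edgeR), with 0, 0 and 0 reads in NPC and 29, 43 and 158 in IN.

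Progenitor and radial glia genes summed to 4191 ± 1335 CPM in NPC and 4600 ± 1074 in IN (exact permutation p 0.7, n = 3 each). The glial glutamate transporter slc1a3.L was at 416 ± 189 and 351 ± 5.55 CPM, and the radial glial lipid carrier fabp7.L at 342 ± 169 and 371 ± 105. By lowest p, hes1.S, a Notch target, had 528, 1749 and 1 reads in NPC and 53, 77 and 9 in IN, and id3.L 142, 105 and 54 against 800, 77 and 420. Genes of DNA replication summed to 1785 ± 668 and 1982 ± 596 CPM; pcna.L, the sliding clamp, was at 216 ± 108 and 392 ± 118. orc6.L had 0, 1 and 0 reads against 175, 36 and 38, and fen1.L 135, 21 and 1131 against 6, 2 and 82. Mitosis genes summed to 1227 ± 806 and 1385 ± 684 CPM. ube2c.L, which acts with the anaphase-promoting complex, had 3, 2 and 0 reads in NPC and 373, 89 and 276 in IN, and aurkb.S, a mitotic kinase, 13, 0 and 0 against 383, 6 and 120. Left out in turn, NPC replicate 3 or IN replicate 1 brought the mitosis list past the threshold (camera adjusted p 0.0187 and 0.0201, 0.983 and 0.846 with an estimated correlation).

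Genes of neuronal commitment summed to 11040 ± 2552 CPM in NPC and 9081 ± 1320 in IN, while 33 of its members had a fold change above 0 and 31 below, and camera put the list higher in IN (adjusted p 0.944). gap43.L, a growth cone protein, was at 1922 ± 683 and 1366 ± 253 CPM, elavl4.S, a neuronal RNA-binding protein, at 328 ± 164 and 143 ± 27.3, and stmn4.S at 352 ± 227 and 105 ± 50.4. Synapse genes summed to 10560 ± 774 and 9166 ± 1161 CPM, with shank1.S, a postsynaptic scaffold, at 213 ± 141 and 80.8 ± 29.3, and nefl.L, a neurofilament, at 53, 3 and 54 reads against 3349, 6 and 43. GABAergic genes summed to 2314 ± 136 and 1775 ± 280 CPM, an IN to NPC ratio of 0.767 without overlap (exact permutation p 0.1, adjusted 0.971); gad1.1.S, which makes GABA, was at 344 ± 190 and 172 ± 58.9 CPM, and calb2.S had 14, 0 and 1 reads against 35, 0 and 197. The more abundant copy gad1.1.L was at 633 ± 88.5 and 547 ± 107 CPM, and gad2.L at 332 ± 183 and 279 ± 158. Glutamatergic genes summed to 939 ± 283 and 766 ± 196 CPM, with the vesicular transporter slc17a7.S at 160 ± 146 and 41.3 ± 13.1 and tbr1.L at 41.1 ± 47.3 and 6.67 ± 5.86. Neurotransmitter receptors summed to 3869 ± 1091 and 3582 ± 1598 CPM, where grin2d.S had 286, 836 and 885 reads against 293, 7 and 130. Voltage-gated channels summed to 4094 ± 636 and 4032 ± 1436 CPM, where kcna2.L had 20, 23 and 10 reads against 5, 5 and 777, and cacna2d3.S 10, 4 and 6 against 11, 243 and 51. Summed over lists, 2 of 34 sums did not overlap between groups, against 3.4 by chance.

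**Figure D2:**
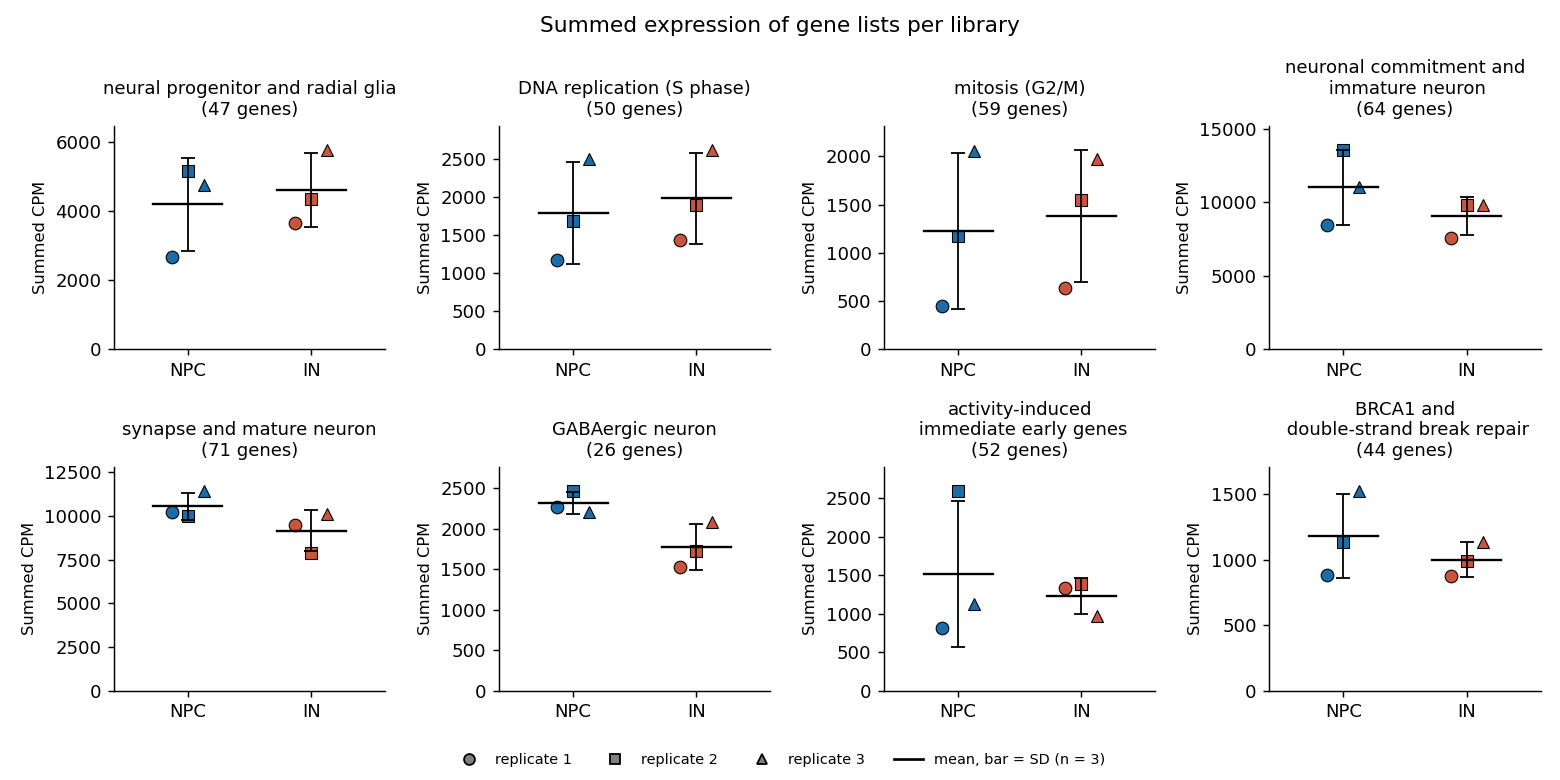
Summed TMM-scaled CPM (vertical axis) of the tested genes of 8 lists in each library (points, shaped by replicate number), with the mean (line) and SD (bar, n = 3). Groups overlap except for GABAergic genes (2314 against 1775 CPM). Libraries numbered 1 are the lowest of their group in the progenitor, DNA replication, mitosis, neuronal commitment and double-strand break repair panels.

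Immediate early genes, which neuronal activity induces within minutes, summed to 1514 ± 950 CPM in NPC and 1230 ± 230 in IN. fos.S was at 166 ± 220 and 62.5 ± 49.4 CPM, ctgf.L had 17, 4 and 0 reads against 172, 256 and 261, and dusp1.L, an ERK phosphatase, 0, 5 and 41 against 136, 161 and 505. Genes of double-strand break repair summed to 1183 ± 322 and 1001 ± 131 CPM; fancd2.L, a Fanconi anaemia protein, had 50, 133 and 461 reads in NPC and 10, 2 and 3 in IN, and rnf168.L, a ubiquitin ligase at breaks, was at 122 ± 100 and 25.1 ± 14.4 CPM. ERK-ELK1-SRF genes summed to 2203 ± 503 and 1935 ± 384 CPM, with mcl1.L, an anti-apoptotic protein and ELK target that also belongs to the apoptosis list, at 1.71 ± 1.34 and 43.3 ± 24.3 CPM, and etv1.L, an ETS factor, at 46.1 ± 19.2 and 172 ± 148. Apoptosis and p53 genes summed to 1045 ± 168 and 1072 ± 30.2 CPM, where bid.L had 11, 8 and 2 reads against 51, 18 and 756.

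Notch genes summed to 2094 ± 499 CPM in NPC and 2132 ± 52.5 in IN, where psen2.L had 33, 1 and 1 reads against 656, 105 and 5. Wnt genes summed to 3674 ± 287 and 3431 ± 442 CPM, where wnt1.L, a midbrain patterning ligand, had 6, 0 and 2 reads against 14, 326 and 700, and fzd6.S 37, 2 and 0 against 37, 331 and 64. Axon guidance genes summed to 9325 ± 988 and 8903 ± 1539 CPM, with efnb1.L at 256 ± 200 and 118 ± 32.5 and sema4a.S at 19.4 ± 29.3 and 75.8 ± 79.5. Clock genes summed to 928 ± 150 and 1035 ± 210 CPM, with csnk1d.S, a kinase of PER proteins, at 18.4 ± 8.41 and 78.3 ± 35.3 and tef.L at 17.0 ± 15.02 and 0.836 ± 0.639. Thyroid hormone response genes summed to 274 ± 116 and 151 ± 48.3 CPM, a ratio of 0.55 without overlap (exact permutation p 0.1, adjusted 0.971); rxrb.S, a retinoid X receptor, was at 73.8 ± 27.3 and 6.41 ± 6.62, and nr1d1.L at 49.0 ± 43.5 and 10.8 ± 14.5. Neuropeptide genes summed to 644 ± 109 and 643 ± 237 CPM, where cck.L had 74, 37 and 0 reads against 802, 207 and 135, and pdyn.S 50, 0 and 1003 against 33, 83 and 3.

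Chromatin enzymes summed to 9779 ± 1798 CPM in NPC and 9039 ± 1693 in IN. ezh1.S, a Polycomb methyltransferase, was at 7.73 ± 5.17 and 57.5 ± 10.9 CPM, and hdac7.L, a histone deacetylase, at 8.01 ± 7.24 and 58.1 ± 9.56, both without overlap and neither past edgeR's test. Heat shock and unfolded protein response genes summed to 7121 ± 2949 and 6313 ± 2861 CPM, with pdia6.L at 45.6 ± 36.3 and 8.09 ± 6.48 and sdf2l1.L at 3.71 ± 3.82 and 33.9 ± 47.6. Ribosomal protein genes summed to 29800 ± 9488 and 27740 ± 8057 CPM, with rpl6.S at 572 ± 279 and 322 ± 120 and rplp0.S at 200 ± 132 and 96.7 ± 54.6. Respiratory chain genes summed to 6210 ± 1860 and 5889 ± 1820 CPM, where ndufc1.L had 273, 333 and 19 reads against 7, 1 and 3, and ndufa5.S 229, 23 and 106 against 0, 8 and 0. The median, the mean and the camera direction differed in sign for the voltage-gated channel, immediate early, glutamatergic, axon guidance, clock, oligodendrocyte, ependymal and retina lists. The sum and the camera direction differed in sign for the neuronal commitment, immediate early, Wnt, axon guidance, clock, neuropeptide, oligodendrocyte and ependymal lists.

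Genes listed as markers of other cell types, the melanocyte list aside, had reads in both groups. This does not by itself show that those cells were present. In some lists few members passed the filter on reads, such as 6 of 27 microglia and leukocyte genes and 5 of 44 retina and lens genes. Oligodendrocyte genes summed to 230 ± 56.2 CPM in NPC and 174 ± 46.0 in IN, where gpr17.L had 288, 0 and 192 reads against 6, 20 and 6, and erbb3.L 789, 19 and 101 against 54, 56 and 110. Microglia and leukocyte genes summed to 25.2 ± 11.98 and 42.0 ± 13.7 CPM, where coro1a.S had 2, 39 and 2 reads against 121, 104 and 306, and c1qb.L 1, 3 and 27 against 262, 55 and 9. Endothelial genes summed to 271 ± 124 and 135 ± 29.4 CPM, where cldn5.L was at 77.2 ± 43.8 and 25.04 ± 17.8 and stab2.L had 6, 3 and 2 reads against 143, 42 and 40. Mural and fibroblast genes summed to 372 ± 93.8 and 380 ± 82.5 CPM, with col5a2.L at 68.2 ± 46.4 and 21.2 ± 30.4 and acta2.S at 0, 147 and 107 reads against 2, 1 and 29. Erythroid genes summed to 470 ± 441 and 347 ± 256 CPM and were low in both libraries numbered 3 (33.1 and 52.7 CPM); hbg2.L had 22, 631 and 0 reads against 0, 22 and 0, and alas2.S 26, 319 and 6 against 52, 31 and 2. Retina and lens genes summed to 20.6 ± 10.02 and 28.9 ± 18.4 CPM, with guca1a.S at 114, 3 and 1 reads against 11, 309 and 88. Skin genes summed to 392 ± 224 and 389 ± 294 CPM, where dsc3.S had 74, 2 and 32 reads against 17, 77 and 793, and itln1.S 108, 4 and 103 against 13, 10 and 0. Ependymal genes summed to 407 ± 176 and 316 ± 118 CPM, where rsph9.L had 0, 905 and 54 reads against 3, 98 and 0, and dnai1.L 281, 471 and 1 against 26, 130 and 11. Choroid plexus genes summed to 223 ± 68.0 and 207 ± 173 CPM, where slc13a4.L had 65, 66 and 791 reads against 35, 69 and 1, and otx2.S 180, 508 and 497 against 23, 261 and 32. Their other copies had higher means in IN, slc13a4.S at 19.9 ± 23.2 and 50.6 ± 34.1 CPM and otx2.L at 54.3 ± 28.4 and 122 ± 135. The 3 skeletal muscle genes tested summed to 17.8 ± 4.24 and 21.2 ± 1.56 CPM, with myh6.S at 0, 11 and 80 reads against 0, 0 and 209 and myh6.L at 0, 104 and 4 against 80, 46 and 2. Of 13 melanocyte genes, 0 passed the filter on reads. None of these lists or genes passed its test over all lists or genes.

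The share of reads in coding sequence was close between libraries of the same number. Coding sequence held 45.1%, 55.1% and 61.0% of mRNA reads in NPC libraries 1, 2 and 3, and 45.9%, 54.0% and 60.9% in the IN libraries of the same numbers, a difference within a number of at most 1.11 percentage points. Spearman correlations over genes, which are not independent replicates, ran from 0.592 to 0.656 (mean 0.627) between groups within a number. They ran from 0.56 to 0.614 (mean 0.59) between groups with other numbers, and from 0.561 to 0.633 (mean 0.592) between libraries of 1 group. The mean was thus highest within a number, although the ranges overlapped.

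**Figure D3:**
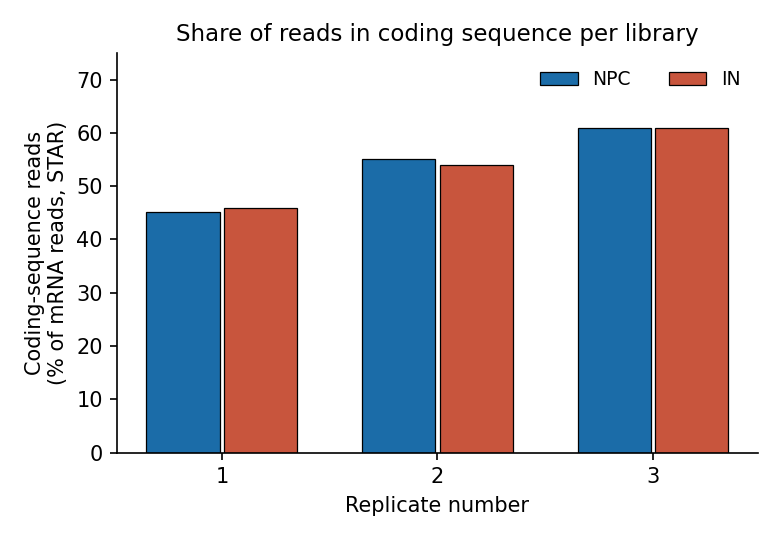
Reads counted over coding sequence as a percentage of reads counted over mRNA (vertical axis, STAR) for NPC and IN libraries by replicate number; each bar is 1 library. The bars of a number differ by at most 1.11 percentage points, and the means of the numbers run from 45.5% to 60.9%.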

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

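The filter at a mean of 50 CPM and the summed-CPM test were chosen after the data were seen; the other alternatives were planned. The count of 0 genes by edgeR held under both other scalings, filters of 1 CPM in 3 libraries (19258 genes) and of a mean of 50 CPM (4517 genes), limma-voom, both coding-sequence tables, summed L and S copies and thresholds of 0.01 and 0.1. Without a filter 16 genes passed (4 higher in IN, 12 higher in NPC), with the cause not tested. In 9 of these 16, 1 group held at most 3 reads in total. In most of the 16, 1 library held nearly all reads, as for aanat.S (0, 0 and 1 in NPC, 1288, 1 and 1 in IN). With DESeq2 88 genes passed (44 and 44). DESeq2 made 127 false calls in the simulated counts, so its 88 calls are not set apart from false ones. It gave 68 to 225 genes in other splits of the 6 libraries, and 68 to 83 in those that, like the real split, kept no number together. Leaving out 1 library gave 0 to 2 genes, 0 to 2 higher in NPC and 0 higher in IN: snx16.S without NPC replicate 1 (1 gene), and snx16.S and tm7sf3.S without NPC replicate 3 (2 genes), named after their values were seen. Lists ran from 0 to 1 (mitosis without NPC replicate 3 or IN replicate 1), and fry in either direction gave 1. The main fit took no pairs, as planned, because the labels give no block. Same-numbered libraries deviated together with r of 0.115, 0.047 and 0.081, the first above the threshold of 0.1 set for pairing. In these deviations each library's highest r with the other group was with its own number, so pairing by number is not excluded. With the replicate number as a block 0 genes passed (645 at an unadjusted p under 0.05) and 0 lists.

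Leaving out 1 library, brca1.L ran from -2.69 to -2.21, elk1.S from -2.28 to -1.33 and elk1.L from -1.79 to -0.36. With coding counts elk1.S was -7.00 (TopHat2) and -9.23 (STAR, where 1 IN read in total makes the fitted value depend on the prior count). Fold changes turned, with the cause not tested, for elk1.L (0.74 with STAR and 0.96 with TopHat2 coding counts), cldn5.L (1.77 and 1.96 with the same tables) and tbr1.L (0.005 with TopHat2). With the replicate block kcna2.L turned to -0.59, myh6.S to -1.42 and myh6.L to 0.31. With limma-voom myh6.S was -1.23 and myh6.L 1.599, and with upper-quartile scaling myh6.L was 0.10. Leaving out 1 library, alas2.S ran from -3.10 to 0.69 (without NPC replicate 2), rsph9.L from -7.94 to 0.006 (without NPC replicate 2), pdyn.S from -4.62 to 0.60 (without NPC replicate 3), nefl.L from -0.76 (without IN replicate 1) to 5.30, kcna2.L from -2.02 (without IN replicate 3) to 4.26, myh6.S from -8.12 (without IN replicate 3) to 3.36, and myh6.L from -0.89 to 4.03 (without NPC replicate 2; 0.48 without IN replicate 3). With L and S copies summed, fzd6.S was -0.15, myh6.L 0.48 and otx2.S 0.37. Of 1350 fold changes of 87 named genes, 1302 kept direction and side of the threshold, 26 newly passed and 22 turned, in 12 genes. Of 1142 list sums, 1012 moved by less than 1 SD between replicates. The 95% interval of the median gene reached 2.94 log2 units to each side. In counts simulated at the depths of these libraries, edgeR recovered 5% of genes changed 4-fold with the estimated dispersion and 100% with a dispersion of 0.05. In the simulation, depth alone therefore did not limit recovery.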

Other observations

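The comparisons between replicate numbers, the grouping of the splits by number and the batch test of the coding share were chosen only after the result was seen. The other tests were set before the result each measures was seen.

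With the group as a term, 8 of 34 lists differed between the libraries numbered 1 and the others (camera, preset correlation). Mitosis genes (median log2 difference -1.44, quartiles -3.16 and -0.65, adjusted p 7.83e-06) and DNA replication genes (-1.30, quartiles -2.43 and -0.08, adjusted p 0.000183) were lower in number 1, with mitosis sums of 447 and 633 CPM in number 1, 1177 and 1551 in number 2 and 2056 and 1971 in number 3. Ribosomal, respiratory chain, heat shock and neuronal commitment lists were lower too, and neurotransmitter receptors (median 0.93) and voltage-gated channels (0.84) higher. None of the 8 held with an estimated correlation (adjusted p 0.303 for each). The medians were the same with genes at 0 on 1 side set to a floor of 3 reads over that side. Number 3 differed from the others in 5 lists: mitosis (median 1.40, adjusted p 7.48e-05, camera), DNA replication (1.01) and mural (1.16) genes higher, and erythroid (-3.20) and receptor genes (-0.665) lower. The others here include the libraries numbered 1, so the mitosis, DNA replication and receptor differences of number 3 are not separate from those of number 1. Number 2 differed in 2, with ribosomal (0.41) and erythroid genes (1.43) higher, again against a side that includes number 1. Of these 5 and 2 lists, 0 and 0 held with an estimated correlation, and 2 (mitosis 1.39, erythroid -5.51) and 2 held with coding-sequence counts. The receptor list of number 3 turned with coding-sequence counts (median 0.075). The mural list of number 3 was not called with the trend with transcript length taken out (adjusted p 0.143, camera on edgeR statistics). That form was not run with the trend left in, so the loss cannot be assigned to length.

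Transcript length and counting in untranslated regions were weighed for the 8 lists of number 1; no biological explanation was tested, as the labels give the numbers no meaning. After the length trend was taken out, 100% of them stayed past the threshold in the same direction. That test used a form of camera on edgeR statistics and was not run with the trend left in. It also called lists that the first test had not, such as progenitor genes (adjusted p 0.0695 by camera, 0.00548 by this form). A change in p between the tests therefore does not measure the effect of length, and staying past the threshold cannot decide whether length contributes. With coding-sequence counts 25% of the 8 lists stayed past the threshold, mitosis (median -1.82) and DNA replication (-1.11). Untranslated reads may thus contribute to the pattern, although all 8 kept their direction. Of the 6 that lost the call, 4 had medians over 1.5 times smaller: ribosomal from -0.855 (quartiles -1.03 and -0.42) to -0.436 (-0.69 and -0.08), receptors from 0.93 (0.29 and 1.67) to 0.54 (-0.635 and 1.502), heat shock from -0.92 (-1.71 and -0.07) to -0.59 (-1.22 and 0.33) and respiratory chain from -0.65 (-1.49 and 0.18) to -0.29 (-1.29 and 0.53). Channels went from 0.84 (0.18 and 1.16) to 1.05 (-0.22 and 2.05), with a wider spread, and neuronal commitment from -0.45 to -0.47.

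The coding share differed by at most 1.11 percentage points between the libraries of a number. Without the 2 most abundant genes the range between numbers was 18.9 percentage points against 15.5 with them, which argues against a few dominant genes. Pairing by number gave the smallest mean difference within pairs, 0.673 points against 4.53 for the next, so that 1 of 6 pairings was as close. The pairing restates the closeness within a number, which was seen first, and is no separate test of it. A batch shared by libraries of 1 number may be the source; the labels record none, and a biological difference shared by a number would give the same values, so the cause stays open.

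Many genes were on in one library of a group and nearly absent in another. Such cases, at least 100 reads in one library and at most 1 in another, numbered 2951 (1788 in NPC and 1163 in IN), 9.56% of the 30867 that could show one. Of the 1306 cases with at least 100 TopHat2 coding reads in the high library, 98.9% were also seen there (the low library at or under 1% of the high), which argues against the aligner for those cases (the counted feature was not tested). Deviations of L and S copies of a gene were weakly correlated (r 0.073, bootstrap interval 0.058 to 0.089, over 5608 pairs, against 0.686 for their mean levels). That r covered all pairs, not the cases alone, and spread particular to each copy lowers it. It therefore cannot decide whether regulation shared by both copies contributes. Few starting molecules per transcript may contribute, but both copies were absent together 217 times against 172.7 expected, a ratio of 1.26, just outside the range set for independence, so this stays open. Regulation that differs between copies was not tested.

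The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. edgeR gave 0 genes in the real split and at most 0 in the others (10 of 10 as large), and camera 0 lists in the real split and at most 9 (10 of 10). DESeq2 gave 88 genes in the real split and at most 225 in the others (7 of 10 as large), list sums without overlap were 2 and at most 7 (9 of 10), and the covariance of L and S fold changes was 0.0662 and at most 0.267 (5 of 10). The 4 splits that kept the libraries numbered 1 together gave 127 to 225 genes by DESeq2 and 3 to 9 lists (preset correlation), and the 5 other splits 68 to 119 genes and 0 to 1 list. The covariance was 0.196 to 0.267 in those 4 and 0.0157 to 0.0547 in those 5, so that of the real split lay between. Every split with more DESeq2 genes than the real one kept 2 numbers together, and so carried differences between numbers. The splits that, like the real one, kept 0 numbers together gave 79, 68 and 83 genes by DESeq2. Their covariances were 0.023, 0.0157 and 0.0433. The real split was the highest of these on both measures, but they are too few for a test. Grouping the splits by number restates the difference of number 1 given above and is no separate test of it, and DESeq2 made 127 false calls in the simulated counts.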
